A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

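RNA from budding yeast cultures was compared on 14 Agilent gene expression arrays with 2 dyes. Per the labels, the cells grew to early log phase at 30 °C in synthetic complete medium with 2% glucose. They then received 100 nM rapamycin, an inhibitor of TORC1, the kinase complex that promotes growth when nutrients are ample. The strains were Y2092, a strain without RIM15 (rim15) and a strain without IGO1 and IGO2 (igo12). Each was sampled after 20, 60, 120 and 180 min of rapamycin, with 1 array per strain and time. On these 12 arrays the Cy3 channel held RNA of the same strain from immediately before rapamycin, and the Cy5 channel held the treated sample. On 2 further arrays the Cy5 channel held RNA of an untreated mutant and the Cy3 channel RNA of the W303 strain. The labels describe no dye swap, and they do not state the genotype of Y2092, which was taken as the strain with all 3 genes because the other strains are named for their deletions.

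The authors scanned the arrays with Agilent Feature Extraction A.7.5.1. The deposited scanner files hold intensity values, the mean pixel brightness of each spot and the median of its local background, per the file headers. The deposited files also hold a log10 log ratio of Cy5 to Cy3, which the software had background-subtracted and normalized between dyes with a LOWESS curve. Further deposited columns hold flags of other kinds, which mark outlying spots and spots well above background. The series matrix, as deposited, holds log2 ratios for 5458 probes and equals the scanner's log ratio after a change of the log base.

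The mean signals and local background medians were read for 10263 spots of 6256 genes, each represented by 1 probe; 4007 genes were spotted in duplicate. Control spots and spots that the scanner had marked as outliers in either channel were left out. In R 4.3.3 with limma 3.58.1, the background was corrected by normexp with an offset of 50. The log2 ratios of Cy5 to Cy3 were then normalized within each array by loess with 4 iterations, and duplicate spots were averaged. A gene was tested when it was well above background in at least 1 channel on at least 50% of the arrays of a test. This left 6050 genes for the rapamycin arrays and 5976 for the untreated ones. Symbols were taken from the reference annotation of assembly R64, which holds 5756 of the 6256 genes, and otherwise from the array. The labels give no genome build, and positions were not used in any computation. A log2 ratio after this correction is smaller than the scanner's own: the slope of the latter on the former ran from 1.19 to 1.38 on the rapamycin arrays and was 1.57 and 1.50 on the untreated ones.

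The rapamycin response was tested with limma (lmFit and eBayes, two-sided) on the 3 strain means over the 4 times, against 0, and again at each time. The mutants were tested against Y2092 with limma on the same strain means, 2 cultures against 1, so the lone Y2092 culture was assumed to vary like the mutants. The untreated mutants were tested with limma on their 2 arrays against 0. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Single strains were compared by a rule of size with no p-value: a difference of at least 1 on the log2 scale, which is 2-fold, of one sign at 60, 120 and 180 min. For the untreated arrays the rule was a log2 ratio of at least 1 in size on that array. The overlap of the mutants was set against independent counts and against 100 simulations in which unchanged mutants shared the Y2092 arrays.

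There were 30 gene lists. Among them were the 3 deleted genes, cytosolic ribosomal proteins, ribosome assembly factors, RNA polymerase I and III subunits, mitochondrial ribosomal proteins, targets of nitrogen catabolite repression, retrograde response targets, general stress genes, trehalose, glycogen, stationary phase, autophagy, vacuolar proteases, respiration, the tricarboxylic acid cycle, gluconeogenesis, fatty acid oxidation, hexose transporters, the proteasome, chaperones, amino acid synthesis under Gcn4, G1/S genes, histones, G2/M genes, mRNA decay, a-specific genes, alpha-specific genes, meiosis and marker genes of laboratory strains. For each list the median was compared with 10000 random lists of the same size matched on intensity in 20 bins, with the random seed 20539. Members past each limma test were counted over all genes tested and adjusted over the list alone, each of the 30 lists separately.

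The genes named in the text followed a rule. RIM15, IGO1 and IGO2 came first, and SSA3, HSP12, HSP26, CTT1, GAP1 and SPI1 were always given. The 8 highest and 8 lowest rapamycin responses were taken among genes past the threshold and of one sign on all 12 arrays. For the mutants, the 12 most negative and 8 most positive differences of one sign in both mutants at all 4 times were taken, filled by the smallest p where fewer passed. The 4 most positive and 4 most negative genes by the rule of size were taken for rim15 against igo12 and for each untreated array. From each list the 2 to 4 members with the largest values were taken. Members named to account for a count of 5 or fewer were chosen after their values were seen, as were the 180 min values and the named HXK1, HXT6, HXT7, HSP42 and HSP82. The lists, tests, thresholds, this rule and most alternatives were fixed before the data were examined.

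The alternatives were no background subtraction, normexp with offset 0, the scanner's own log ratio, the series matrix values, median centring in place of loess, loess without ribosomal protein and ribosome assembly genes, scale normalization between arrays, no filter, a filter on both channels, random lists not matched on intensity, an intensity trend with a robust prior, culture as a random block over the 12 arrays, each strain left out, each time left out, only 20 and 60 min, only 120 and 180 min, 1.5-fold and 3-fold rules of size, another strain set apart, and the rule of size at 120 and 180 min only. The limma tests on the rapamycin arrays were also run without the array labelled igo12 20 min. The igo12 mean then covered 60, 120 and 180 min, and those of Y2092 and rim15 all 4 times. Correlations and the choice of named genes were not redone without it. The brightest probe of a gene in place of the mean was not run, because each gene had 1 probe. The limma tests and the rule of size were tested on simulated data. Simulated noise was independent between genes, with spreads drawn from those limma had already smoothed across genes. The shares of changes found may therefore not hold for the real arrays. With 2-fold changes added to about 100 genes, limma called 97 of 100 for the rapamycin response, 81 of 100 for the mutants and 95 of 99 for the untreated arrays, with 12, 13 and 6 false calls among unchanged genes. The median estimate of a true log2 change of 1 was 0.77, 0.73 and 0.77. With 4-fold changes, the rule of size found 78 of 100 genes for rim15 and 77 of 100 for igo12 against Y2092, and 7 and 6 unchanged genes met it. Between the mutants, the same run held no known difference, and 0 of those 100 genes and 6 unchanged genes met the rule. With the changes added to rim15 alone, it found 78 of 100 against igo12, and 8 unchanged genes met it.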

Results

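The data were log2 ratios of transcript signal in Y2092, rim15 and igo12 cells at 4 times of rapamycin, each relative to the same strain before rapamycin, and in the untreated mutants relative to W303. RIM15 encodes a protein kinase restrained by TORC1, and IGO1 and IGO2 encode small paralogous proteins that Rim15 phosphorylates. Each group held 1 array from 1 culture, so there were no replicates of a strain and time, and p-values measure the spread between cultures of different genotype. The median Cy3 signal ran from 92.1 to 212 and the median Cy5 signal from 287 to 581, over backgrounds of 19 to 26. On the rapamycin arrays the Cy3 signal split by strain, at 92.1 to 96.5 in Y2092, 144 to 161 in rim15 and 192 to 212 in igo12. The slope of the scanner's log ratio on the one used here was 1.27 to 1.38, 1.22 to 1.27 and 1.19 to 1.23 in that order. Relative to the scanner's, ratios were thus compressed most in Y2092. Differences between the mutants and Y2092 can hold part of this, which was not taken out. Between 5511 and 6036 genes lay well above background in Cy3 and between 5888 and 6135 in Cy5. The number of arrays limits the precision of every value. Duplicate spots of a gene differed on an array by a median of 0.03 to 0.06 on the log2 scale.

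The first question was whether each strain lacked the transcripts it was named for. RIM15 (YFL033C, assembly R64, chromosome VI, 69115 to 74427) had a mean log2 Cy5 signal of 9.52 on the Y2092 arrays and 5.88 on the rim15 arrays. In Y2092 its log2 ratio was 0.70, 1.35, 1.32 and 1.22 at 20, 60, 120 and 180 min, and in igo12 it was 1.03, 1.91, 1.91 and 1.88. IGO1 (YNL157W, chromosome XIV, 340352 to 340858) and IGO2 (YHR132W-A, chromosome VIII, 370054 to 370449) had mean log2 Cy5 signals of 5.72 and 5.84 on the igo12 arrays of 60, 120 and 180 min. Their means on the 8 Y2092 and rim15 arrays were 7.86 and 8.75. On the array labelled igo12 20 min the Cy5 signals were 7.79 for IGO1 and 9.14 for IGO2, while the Cy3 signals were 5.93 and 6.45. This Cy5 sample therefore held both transcripts, and the main counts for the mutants over all times are also given without it below. IGO2 averaged 0.42 over time in Y2092 and 0.47 in rim15. Its limma call over the 3 strains (0.50; adjusted p 0.00260) includes igo12, which lacks the gene and whose mean rested on that array (2.69). The call was lost without that array (0.27; adjusted p 0.144) and without the 20 min time point (0.24; adjusted p 0.148), but held over Y2092 and rim15 without igo12 (0.44; adjusted p 0.0162). With culture as a random block the value stayed at 0.50 and the adjusted p was 0.363. RIM15 at 0.93 (adjusted p 0.0741) and IGO1 at 0.19 (adjusted p 0.0683, scanner 0.58) did not pass in limma. Both tests include a strain that lacks the gene, rim15 for RIM15 and igo12 for IGO1. The igo12 mean of IGO1 includes 1.86 from the array labelled igo12 20 min. In the untreated mutants against W303, the ratios were -1.75 for RIM15 in rim15, and -1.36 for IGO1 and -2.00 for IGO2 in igo12. Because the mutant channel was at background, these correspond to RIM15 at least 3.20-fold lower, IGO1 at least 2.34-fold lower and IGO2 at least 3.45-fold lower.

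**Figure D1:**
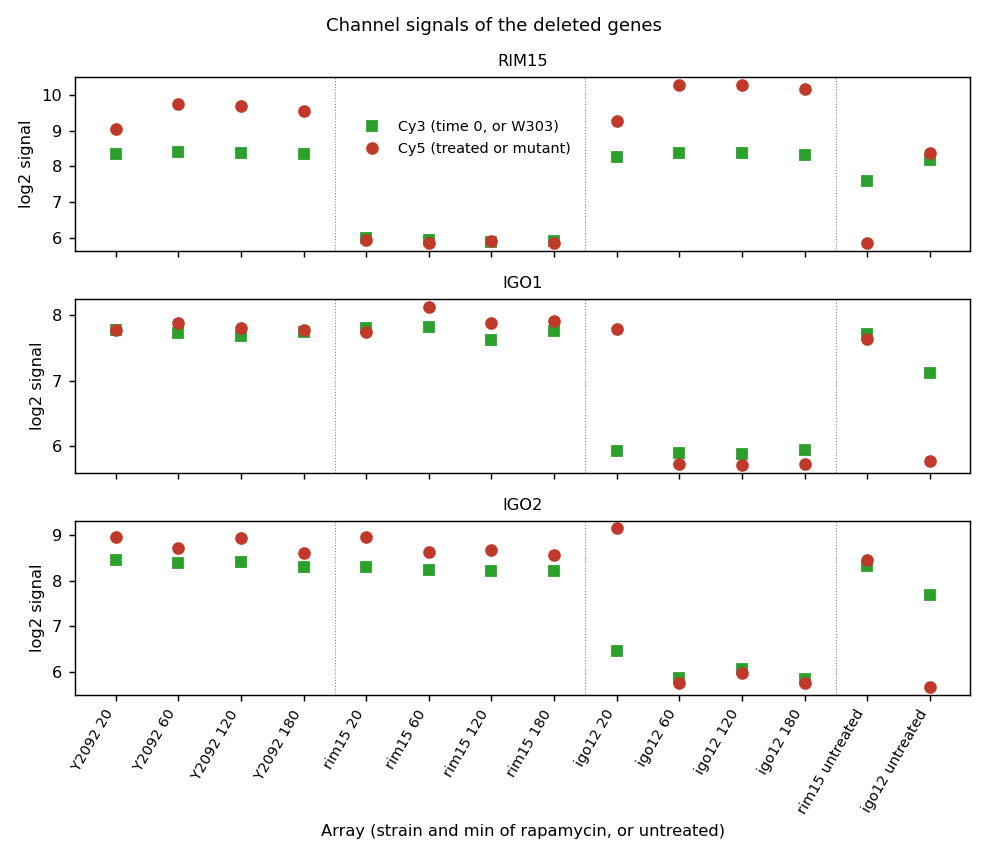
Log2 signal in Cy3 (squares) and Cy5 (circles) of RIM15, IGO1 and IGO2 on the 14 arrays, ordered by strain and time. The Cy5 signals of IGO1 and IGO2 on the array labelled igo12 20 min were 7.79 and 9.14, against means of 5.72 and 5.84 on the other 3 rapamycin arrays of that strain.

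The second question was what rapamycin changed in all 3 strains. Transcripts for making ribosomes fell most. Of 138 genes for cytosolic ribosomal proteins, 137 fell and RPL15B rose (0.26), with a list median of -3.21. Of 86 ribosome assembly factors all fell (median -2.54), and so did all 19 subunits of RNA polymerases I and III (median -1.64, scanner -2.53). The lowest means were those of NSR1, a nucleolar protein for ribosomal RNA processing (-4.65, SD 0.40, n = 3 strains; adjusted p 0.000145), RPL22A (-4.56), RPS9B (-4.43, SD 0.07; adjusted p 3.606e-05), RPS22A (-4.36), URA7, a CTP synthase (-4.28), RPL9A (-4.17), RPS3 (-4.04) and RPL38 (-4.01). Among assembly factors MAK16 and NOG1 stood at -3.95 and NOP56 at -3.80, and among polymerase subunits RPA135 at -3.52 and RPA34 at -3.50. Early values of both groups stood apart, a difference that was not tested: in Y2092 the ribosomal protein median was -1.01 at 20 min and -3.75 at 60 min, while that of the assembly factors was -2.80 and -2.67. In rim15 the ribosomal protein median went from -0.90 to -3.53 and that of the assembly factors from -3.13 to -3.05. Mitochondrial ribosomal proteins had a median of -0.31, with 33 of 54 lower, among them RSM26 (-1.09) and MRPL11 (-0.92), and 4 higher (MRPL23, RSM10, RSM19 and RSM22); at 20 min alone 16 were higher and 11 lower.

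Genes for using poor nitrogen sources rose. Of 22 targets of nitrogen catabolite repression, which are off while good nitrogen sources last, 17 rose and GAT1 (-1.09) and MEP3 (-0.97) fell; the median was 2.10. Among genes of one sign on all 12 arrays, the highest mean was that of DAL5, an allantoate permease (5.24, SD 1.18; adjusted p 0.00111). UGA1, a GABA transaminase, rose by 4.46, CPS1, a vacuolar carboxypeptidase, by 4.31, DAL4, an allantoin permease, by 3.35, and GAP1, the general amino acid permease, by 1.579 (SD 0.71; adjusted p 0.00842). Outside the list, ALD2, an aldehyde dehydrogenase (5.19), CHA1, which degrades serine and threonine (5.15), UGA2 of GABA use (4.59), SNZ1 of vitamin B6 synthesis (4.54) and AMD2, a putative amidase (4.29), were among the 8 highest. All 7 retrograde response targets, which supply glutamate precursors, rose (median 2.00), with PYC1 at 3.67, DLD3 at 3.23 and CIT2 at 2.45. Of 32 amino acid synthesis genes under Gcn4, 23 rose (ARG1 3.48, ARG4 3.40, HIS5 2.44; list median 0.74), and ARO4, BAT1, ILV1, ILV2 and ILV3 fell. All 5 vacuolar proteases rose (median 1.71; PRB1 2.41, PEP4 1.71). Of 36 autophagy genes, 31 rose (median 0.67, or 1.34 with the scanner's log ratio; ATG8 2.21, ATG39 1.83, scanner 3.26) and ATG10 and ATG27 fell.

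Stress and reserve genes rose in most members. Of 35 general stress genes, 31 rose and none fell, with a median of 1.03 (1.72 with the scanner's log ratio); HSP104, HXK1, TSL1 and YGP1 did not pass. The cytosolic catalase CTT1 rose by 1.34 (SD 0.10; adjusted p 0.000226; scanner 2.18), the small heat shock protein HSP26 by 1.79 (SD 0.76; adjusted p 0.00700; scanner 2.84) and the membrane protein HSP12 by 0.80 (SD 0.28; adjusted p 0.00482; scanner 1.82). The Hsp70 gene SSA3 (0.23; adjusted p 0.101) and the cell wall gene SPI1 (0.14; adjusted p 0.121; scanner 0.38) did not pass; SSA3 passed with the scanner's log ratio (0.44). Of 7 trehalose genes 6 rose (median 0.61; NTH1 2.12, ATH1 0.99, scanner 1.79), of 13 glycogen genes 9 rose (median 0.68, scanner 1.52; GPH1 1.86, GSY2 1.31), and of 13 stationary phase genes 10 rose (median 0.89, scanner 1.57). Carbon genes of the respiratory state also rose: 9 of 10 genes of the tricarboxylic acid cycle (median 0.74; CIT1 2.00), 10 of 11 of gluconeogenesis and the glyoxylate cycle (median 0.83, scanner 1.85; FBP1 1.26, scanner 2.73), 10 of 11 of fatty acid oxidation (median 0.55, scanner 1.29; PXA2 1.23, scanner 2.10) and 21 of 34 of respiration (median 0.30, scanner 0.48; COX5B 1.88, SDH4 1.37), where ATP1 fell (-0.22). Malate synthase MLS1 had a mean of 3.66 (scanner 5.97), its Cy3 spot in Y2092 at 180 min being near background (at least 6.13-fold higher there). Of 7 hexose transporters HXT1 (-2.08), HXT2 (-2.62), HXT3 (-0.67) and HXT4 (-1.23, scanner -2.20) fell and HXT5 (0.73) rose.

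Most cell division genes fell. Of 9 histone genes 7 fell over the 4 times (median -1.17; HTA2 -1.48, HTB2 -1.41), although at 20 min alone 5 rose and 0 fell. Of 13 G2/M genes 11 fell (median -0.71; CLB1 -1.29, CLB2 -1.24, scanner -2.06) while DBF2 (0.52) rose, and of 26 G1/S genes 21 fell (median -0.48; RNR1 -1.75, POL30 -1.16, CLN1 -1.16). Of 21 mRNA decay factors 14 fell (median -0.35; PUB1 -1.22, EDC3 -0.97) and DCP2 and EDC2 rose. Chaperones had a median of -0.33, which turned to 0.13 with median centring: 8 of 18 fell (SSA2 -1.60, YDJ1 -1.49) and HSP26, HSP42 (1.27), HSP78 (1.34) and SSA4 (0.69) rose. The proteasome median was 0.01 and changed sign among alternatives, with 10 of 33 subunits higher (SCL1 0.55) and RPN10 and RPT4 lower; at 60 min alone 2 were higher and 19 lower.

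In total 4181 of 6050 genes passed in limma, 2094 higher and 2087 lower. Of these, 1701 higher and 1753 lower genes had one sign on all 12 arrays. At an unadjusted p under 0.05 there were 4352, where chance gives 302. At 20, 60, 120 and 180 min alone, 1987, 2142, 1996 and 1851 genes rose and 1989, 2182, 2029 and 1876 fell. Adjusted over the list alone, the counts differed from these in some lists; for example, 18 nitrogen genes rose and 3 fell, 19 respiration genes rose and 1 fell, and 6 proteasome genes rose and 1 fell. The dyes were not swapped, so a dye bias of a probe that recurred on every array would enter this test. Loess centres the ratios of each array near 0, so the near-equal numbers of higher and lower genes follow in part from the normalization. With median centring 4061 genes passed. Of the 4181 genes above, 3022 then passed with the same sign, and 416 had the opposite sign. With the scanner's log ratio these numbers were 3930 and 0.

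**Figure D2:**
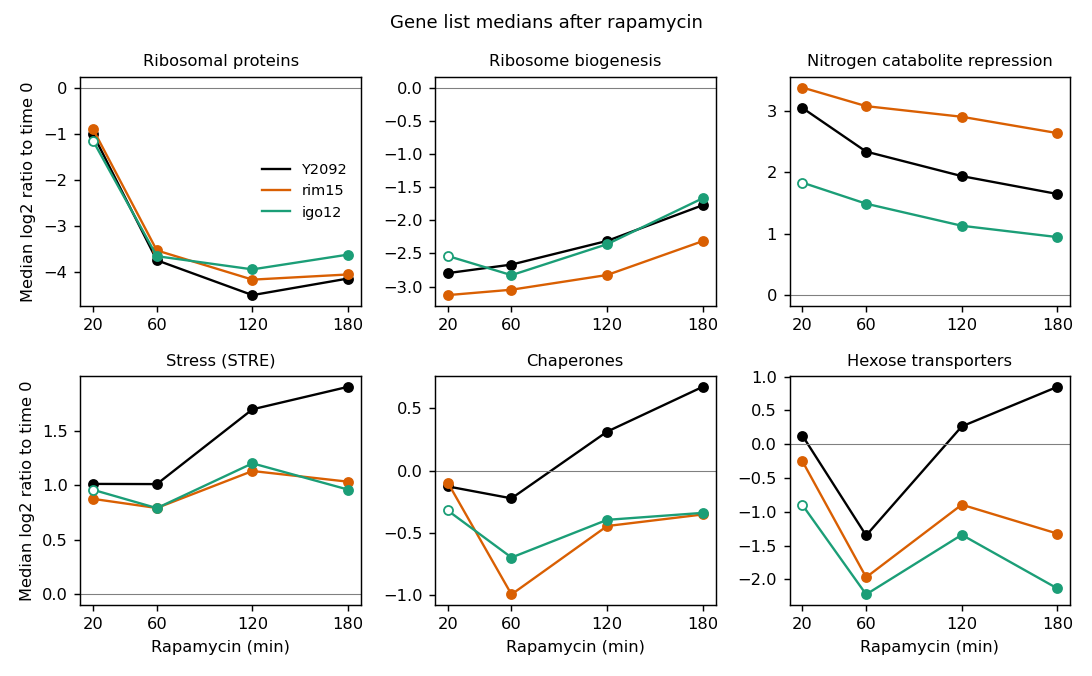
Median log2 ratio of 6 gene lists (vertical axes) against min of rapamycin (horizontal axis) in Y2092, rim15 and igo12, with an open circle for the array labelled igo12 20 min. At 180 min the general stress median was 1.90 in Y2092, 1.03 in rim15 and 0.96 in igo12, and the chaperone median 0.67, -0.35 and -0.34; the chaperone median over all strains and times changed sign with median centring.

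The third question was which parts of the response depended on Rim15 and on Igo1 and Igo2 together. No gene passed in limma for the mutants against Y2092 (0 higher and 0 lower of 6050; lowest adjusted p 0.197). At an unadjusted p under 0.05 there were 1228, 701 higher and 527 lower in the mutants, where chance gives 302. Without the array labelled igo12 20 min there were 688 (lowest adjusted p 0.419 in limma). That setting kept 20 min in Y2092 and rim15, so the strain means covered different times. With 20 min left out of every strain there were 1431 (lowest adjusted p 0.117 in limma). Limma with an intensity trend and a robust prior called 155, 104 higher and 51 lower. Limma over the 12 arrays with culture as a random block called 1386. Its p-values cannot be relied on here, because they count 12 arrays where the comparison rests on 3 cultures. Adjusted over the list alone, 16 of 18 chaperones were lower in the mutants (median difference -0.71, all 18 below 0), below every one of the random lists. Random lists do not keep together genes that vary together. A rank among them, here and for other lists, therefore does not measure the spread between cultures. The most negative difference among chaperones was that of HSP104, a disaggregase (-1.53, SE 0.10; adjusted p over all genes 0.197), whose ratio at 180 min was 2.64 in Y2092, 0.56 in rim15 and 0.32 in igo12. Differences for other chaperones included HSP82 (-1.06), CPR6 (-0.93), HSP42 (-0.90), HSP78 (-0.86), STI1 (-0.81) and SIS1 (-0.80), none past the threshold over all genes.

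Among 35 general stress genes, 18 were lower and PAI3 (0.40) was higher, adjusted over the list alone, with a median difference of -0.46 (scanner -0.72). That difference was 0.08 at 20 min and grew from -0.16 at 60 min to -0.63 and -1.12 at 120 and 180 min. The 20 min value includes the array labelled igo12 20 min, whose sample held IGO1 and IGO2. It therefore cannot show whether the difference was absent at 20 min. At 180 min HSP26 stood at 4.90 in Y2092, 1.53 in rim15 and 1.86 in igo12. Its mean difference was -1.22 (SE 0.28, adjusted p 0.212 in limma), turning to 0.10 at 20 and 60 min alone, which include that array. HSP12 stood at 2.43, 1.07 and 1.22 (mean difference -0.46, scanner -1.19) and SSA3 at 1.31, 0.24 and 0.19 (mean difference -0.39, scanner -0.61). CTT1 had nearly equal ratios of 1.22, 1.15 and 0.96, and its mean difference of 0.14 turned to -0.24 with the scanner's log ratio. GAP1 stood at 1.52, 1.40 and 0.29 (mean difference -0.52, or 0.12 for rim15 alone), and SPI1 had a mean difference of -0.19 (0.27 with median centring). The differences of the deleted genes themselves were -0.33 for RIM15, 0.17 for IGO1 and 0.12 for IGO2. Each averages a mutant that lacks the gene with one that has it, and RIM15 was 0.53 for igo12 alone. Without the array labelled igo12 20 min, IGO1 and IGO2 turned to -0.08 and -0.23.

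**Figure D3:**
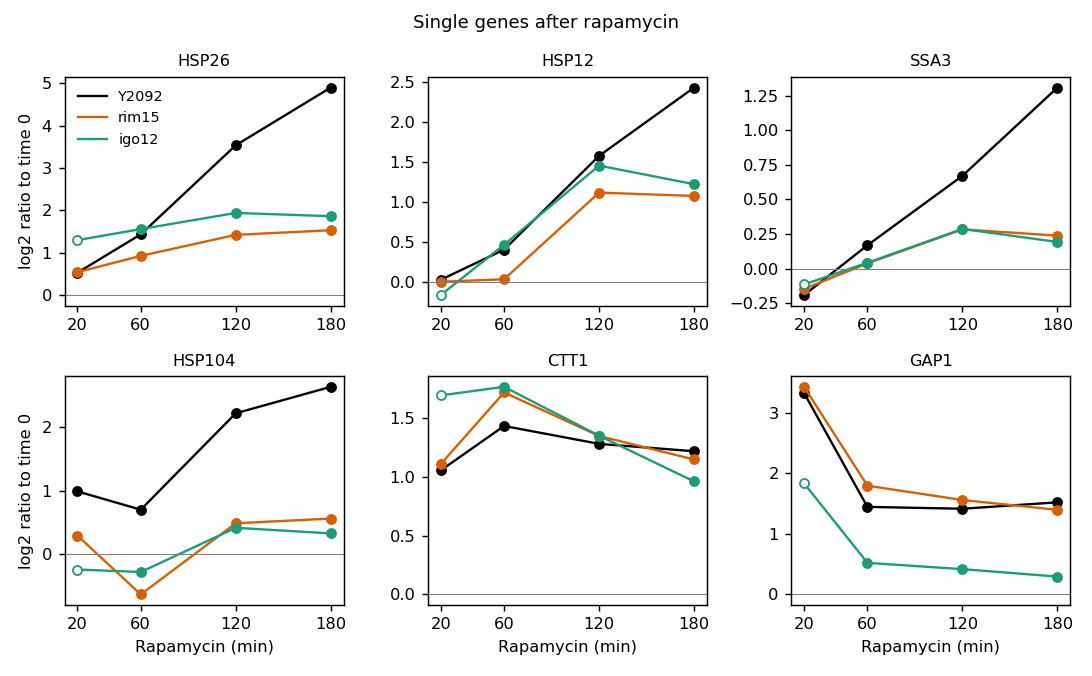
Log2 ratio (vertical axes) of 6 genes against min of rapamycin (horizontal axis) in the 3 strains. At 180 min HSP26 stood at 4.90 in Y2092, 1.53 in rim15 and 1.86 in igo12, whereas CTT1 stood at 1.22, 1.15 and 0.96.

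Responses of genes of sugar uptake and of the tricarboxylic acid cycle were also lower in the mutants by this adjustment. All these differences are between ratios to each strain's own time 0. Some of the genes were higher in the untreated mutants, as given below, and this was not taken out of the differences. Adjusted over the list alone, HXT3 (-0.83), HXT4 (-0.91), HXT6 (-1.57) and HXT7 (-1.74) were lower among 7 hexose transporters (median difference -0.83). HXT7, a high-affinity transporter, stood at 180 min at 1.33 in Y2092, -1.32 in rim15 and -2.13 in igo12, and the hexokinase HXK1 at 1.51, -0.72 and -1.501. Over the list alone, 6 of 10 genes of the tricarboxylic acid cycle were lower (median difference -0.46; ACO1 -0.58, IDH2 -0.56, MDH1 -0.54), and so were ACO1, IDH1 and IDH2 of the 7 retrograde targets (median -0.56). The glycogen genes GPH1 (-0.66), PGM2 (-0.85, scanner -1.57) and UGP1 were lower (list median -0.29, scanner -0.65). In the proteasome 15 of 33 subunits were lower over the list alone (median -0.29; RPN9 -0.86, RPN6 -0.74), but 0 with the scanner's log ratio. The same adjustment gave 5 of 13 G2/M genes lower (BUD4, CDC5, CLB1 -0.73, CLB2 -0.90 and KIN3; median -0.26). Opposite to these, 5 of 11 genes of gluconeogenesis and the glyoxylate cycle were higher in the mutants (CRC1, FBP1 0.65, ICL1, JEN1 0.62 and MLS1 1.31, scanner 0.62; list median 0.49).

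The ribosomal protein median was 0.20, above every one of the random lists, but -0.15 with median centring and -0.10 without the array labelled igo12 20 min, with RPL41A (1.18) and RPL41B (1.12) higher over the list alone. The setting without that array left 20 min out of igo12 alone. When 20 min was left out of every strain, the sign of the median did not turn. The nitrogen median was -0.02 and changed sign among alternatives, with 0 members past either adjustment; it was 0.82 for rim15 alone. By the rule of size 6 nitrogen genes were higher in rim15 and 4 lower in igo12 (DAL3, DAL80, MEP2 and PUT4) than in Y2092. The fixed nitrogen list held 23 genes, of which 22 were matched on the array. It named DUR1,2, which has the symbol DUR12 here and so was left out of every nitrogen count. DUR12 was also lower in igo12 than in Y2092 by this rule. Over the list alone, MOH1, SNO1, SNZ1 and SNZ3 were higher and SSA3 was lower among stationary phase genes, ATG5 (0.94) and ATG22 (0.77) were higher among autophagy genes, and MF(ALPHA)1 (-0.49) was lower among alpha-specific genes. The medians of the stationary phase, autophagy and alpha-specific lists, 0.01, 0.08 and 0.01, changed sign with the scanner's log ratio. Among genes of one sign in both mutants at all 4 times, the 12 most negative differences also included YCP4 (-0.69), LSP1 of eisosomes (-0.76), RTT107 of DNA repair (-0.66) and ARA1, an arabinose dehydrogenase (-0.66), and the 8 most positive were those of YGL088W (1.79), YOL013W-A (1.63), HXT17 (1.576), BIO5 (1.43), YIL100W (1.43), ECM22 (1.41), YGR114C (1.28) and YOR121C (1.26), all with an adjusted p of 0.197 or 0.198. Several of these were low in the untreated mutants: YGL088W at -2.12 in rim15 and -1.26 in igo12, YOL013W-A at -1.72 and -1.43, HXT17 at -1.51 and -1.04.

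Fewer members of the mutant lists passed with the early times alone, which include the array labelled igo12 20 min. The time and the doubtful sample are therefore not separated. With 20 and 60 min alone the lower counts over the list alone were 7 chaperones, 1 stress gene and 0 for the proteasome, the tricarboxylic acid cycle and the hexose transporters. Without the array labelled igo12 20 min they were 8, 6, 0, 0 and 0, the only higher gene in any list was UGA2 of the stress list, and every other list had 0 in either direction. This setting kept the 20 min arrays of Y2092 and rim15, so the strain means covered different times. Without the 20 min time point of every strain the lower counts were 17, 23, 18, 6 and 4.

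The fourth question was whether the mutants differed from Y2092 in the same genes. By the rule of size, 29 genes were higher and 5 lower in rim15 (UTP6, RIM15, DPH1, HSP104 and HSP82), and 39 higher and 22 lower in igo12. Both mutants shared 22 higher genes, where independence gives 0.187 and the simulated shared control gave a mean of 6.24 and at most 12. The simulated lists of higher genes were smaller than the observed ones (means of 15.8 for each mutant), so the 2 overlaps are not on one footing. The mutants shared 0 lower genes, where independence gives 0.0182 and the simulated shared control gave a mean of 6.1 and at most 12. The simulated lower lists also had another size than the observed ones (means of 15.8 for rim15, against 5, and 16.1 for igo12, against 22). The simulation was even between the directions and the data were not, so it is a weak guide to either overlap. The differences from Y2092, averaged over 4 times, correlated across genes with r = 0.701, and the shared control alone gave a simulated 0.503 with a maximum of 0.606; genes are not independent replicates. The covariance was 0.0617, against a simulated 0.0270 with a maximum of 0.0366, so part of the overlap and of this correlation may come from the shared Y2092 arrays. The middle 90% of mean differences ran from -0.43 to 0.47 for rim15, from -0.40 to 0.51 for igo12 and from -0.34 to 0.26 between the mutants. No p-value can be given for 1 culture against 1, and the counts changed with the size asked for.

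The fifth question was how the mutants differed from each other. By the rule of size 31 genes were higher and 3 lower in rim15 than in igo12. Of 22 nitrogen genes, 14 were among the higher ones, and so were CIT2, DLD3 and PYC1 of the 7 retrograde targets. DUR12, left out of the nitrogen counts, was also higher. The transcription factor gene DAL80 differed by 3.32, 3.001, 3.02 and 3.28 at 20, 60, 120 and 180 min, the proline permease gene PUT4 by 2.56, 2.22, 2.51 and 2.71, the peroxisomal citrate synthase gene CIT2 by 2.27, 2.42, 2.47 and 2.50, and DAL5 by 2.11, 1.92, 2.61 and 2.77. The 20 min values here use the array labelled igo12 20 min, whose sample held IGO1 and IGO2. The 3 lower genes were RIM15 (-1.08, -1.97, -1.90 and -1.93), YGR079W (-1.25, -1.07, -1.30 and -1.32) and RRN11, a factor of RNA polymerase I (-1.25, -1.03, -1.17 and -1.38). At 180 min the nitrogen median was 2.64 in rim15 and 0.94 in igo12, and the retrograde median 2.56 and 1.15. These ratios are relative to each mutant's own time 0. The mutants also differed in these genes on the untreated arrays, but no array sets one time 0 against the other.

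The sixth question was how the mutants differed from W303 before rapamycin. Untreated igo12 had higher nitrogen genes than W303, with all 22 above 0, 13 of them at least 2-fold, and a median of 1.21 (scanner 1.84), where untreated rim15 had a median of -0.04. All 7 retrograde targets were above 0 in igo12 (median 1.09, against 0.21 in rim15). The highest ratios in igo12 were those of DAL5 (2.94), DAL80 (2.80, scanner 4.07), CIT2 (2.46) and the ammonium permease gene MEP2 (2.41). The lowest in rim15 included YMR193C-A (-2.15). By the rule of size 37 genes were higher and 16 lower in igo12, and 0 higher and 21 lower in rim15. In limma on both arrays 0 of 5976 genes passed (lowest adjusted p 0.0593), with 1574 at an unadjusted p under 0.05 where chance gives 299. The number that passed was 229 with normexp offset 0, 222 with the scanner's log ratio, 30 with the filter on both channels and 3543 with median centring. Both arrays had W303 RNA in Cy3. The test leaves out the spread of W303 itself, and a dye bias that recurred on both arrays would enter it. Neither the excess over 299 nor the counts over the list alone below can therefore be laid to the deletions.

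**Figure D4:**
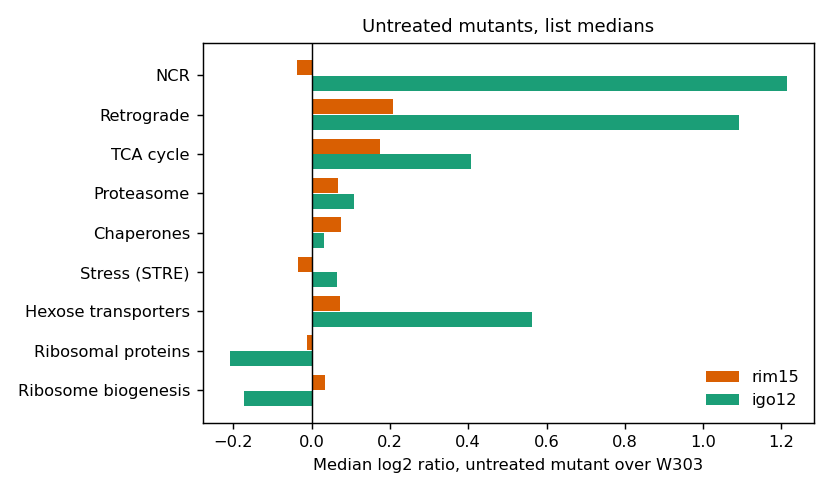
Median log2 ratio of 9 gene lists in the untreated mutants relative to W303, as bars for rim15 and igo12. The nitrogen and retrograde medians were 1.21 and 1.09 in igo12 and -0.04 and 0.21 in rim15, while those of ribosomal proteins (-0.21 in igo12, -0.01 in rim15), ribosome assembly in igo12 and stress genes in igo12 changed sign with median centring.

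Adjusted over the list alone in the untreated mutants, 12 ribosomal protein genes were lower, in a list whose median changed sign with median centring, 6 of 34 proteasome genes were higher (PRE9, RPN3, RPN6, RPN8, RPN9 and RPT1), 4 genes of the tricarboxylic acid cycle (FUM1, IDH1, IDH2 and LSC1) and 4 G2/M genes (CDC5, CLB1, CLB2 and MYO1) were higher, and IDH1 and IDH2 were higher among retrograde targets. HSP104 was higher and SOD2, TFS1 and YGP1 were lower among stress genes; HSP104 stood at 0.47 in rim15 and 0.32 in igo12. Single members of other lists were MRPS9 and DCP1 (higher) and MRPL36, CCR4, RPC11 and ATG22 (lower). The hexose transporter median was 0.56 in igo12 and 0.07 in rim15, and HXT7 stood at 1.14 and 0.32. Adding each mutant's untreated ratio to its response sets the mutants against W303: at 180 min the nitrogen median became 2.47 in igo12 and 2.50 in rim15, with 1.65 in Y2092 relative to its own time 0. The retrograde median became 2.70 in igo12 and 2.76 in rim15, with 2.91 in Y2092. The stress median became 0.93 in igo12 and 0.98 in rim15, with 1.90 in Y2092, and the hexose transporter median -0.991 and -0.999, with 0.85 in Y2092. The chaperone median became -0.27 in igo12 and -0.19 in rim15, with 0.67 in Y2092. No such sum was made for the tricarboxylic acid cycle, the proteasome or the G2/M genes. These sums take the untreated RNA to stand for that of time 0. They rest on 1 untreated array per mutant, and Y2092 was not compared with W303.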

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

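All tests in this part were chosen after the results were seen. 6 values were picked out because every time of one strain had the opposite sign to every time of another; these differences were not tested. RPN9, a subunit of the proteasome lid, ran from 0.20 to 0.85 in Y2092 and from -0.75 to -0.01 in rim15, a difference of means of -0.90, and from -0.64 to -0.04 in igo12, a difference of -0.82. MRPL36 of the mitochondrial ribosome ran from -0.59 to -0.27 in Y2092 and from 0.00281 to 0.15 in rim15, a difference of 0.48. ATG5 of autophagy ran from -0.67 to -0.18 in Y2092 and from 0.00059 to 0.79 in rim15, a difference of 0.92. The median of the marker genes of laboratory strains ran from 0.06 to 0.18 in Y2092 and from -0.21 to -0.01 in igo12, a difference of -0.19, and from 0.20 to 0.50 in rim15, an igo12 minus rim15 difference of -0.47.

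On the array labelled igo12 20 min, IGO1 and IGO2 were present in Cy5. Their signals lay above the mean of the 8 Y2092 and rim15 arrays by 0.16 on the log2 scale, and 100% of their spots lay above the other 3 igo12 arrays, which argues against an artefact of single spots. A minor share of RNA from a strain with both genes would leave the signal far lower, so 0.1562 also argues against that. RIM15 lay 3.40 above its mean on the rim15 arrays, which argues against RNA of the rim15 culture. What stays open is Cy5 RNA from a strain that has RIM15, IGO1 and IGO2, which may be a mislabelled sample. Across genes its ratios correlated with Y2092 at r = 0.939 for 20 min, and 0.868, 0.796 and 0.76 for 60, 120 and 180 min. With rim15 at 20 min, r was 0.956. The profile was thus nearest to those of 20 min, but the sample itself was not identified.

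Of the 22 genes higher in both mutants than in Y2092 by the rule of size, 17 differed mainly in Cy3, the time 0 channel. The labels give the Cy3 of each strain's arrays as its time 0 RNA. Between those arrays the Cy3 signal of these genes had a median SD of 0.41 in Y2092, 0.16 in rim15 and 1.03 in igo12. Without the array labelled igo12 20 min it was 0.26 in igo12. The mean SD over the 3 cultures lay at percentile 100 among matched random lists with or without that array. Signal that varies between hybridizations of the same RNA is thus a candidate explanation for part of a median Cy3 difference of -1.545. On the array labelled igo12 20 min the Cy3 median of these genes was 10.84, against 8.215, 9.06 and 9.05 at 60, 120 and 180 min. Whether its Cy3 held the same time 0 RNA was not tested. Lower time 0 transcript in both mutants could also be involved. The median Cy3 signal of these genes was lower in 7 of 8 pairings of a mutant array with the Y2092 array of its time (down to -1.75). The array labelled igo12 20 min was the exception at 0.40. Except at 20 min, these pairings entered the rule of size, so lower Cy3 in them follows from how the genes were set apart. The untreated medians, -1.21 in rim15 and -1.04 in igo12, did not enter that rule. The explanations cannot be told apart. The 5 that differed mainly in Cy5 (EMA35, NHA1, RTA1, YCR101C and YGR190C) had a median difference of -0.27 in Cy3 and 1.17 in Cy5, a split that follows from how they were set apart, with the SD of their Cy3 signal at percentile 93.9 (98.6 without that array), and no explanation was tested for them. Of the 22 genes 7 were absent from the reference annotation, against 397 of 6050 (Fisher's exact p 0.000357, two-sided).

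Untreated igo12 had high nitrogen and retrograde genes. A mixture of untreated RNA with one share of RNA as after 20 min of rapamycin gave shares of 19% (16.8 to 21.5) from 511 genes lower at 20 min, 18.3% (12.9 to 25.7) from 24 genes of both lists and 10% (8.3 to 11.8) from 238 other higher genes. Because the 20 min profile was assumed from Y2092 and rim15 and the criterion was changed after the shares were seen, a mixture and a change in the cells cannot be told apart. A change of these 2 lists alone is argued against, because the other higher genes had a median of 0.30 (percentile 100), and a dye effect on the probes is argued against by untreated rim15, which differed by -1.11. The state of the igo12 culture at harvest and the deletion itself remain open and untested.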

How the results depend on the processing

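The alternatives normexp offset 0, without the array labelled igo12 20 min, and the rule of size at 120 and 180 min only were chosen after the data were seen; the others were planned. Of 150 alternative counts, 117 stayed within 1.5 times the reported count. A count that stayed does not show that the same genes passed. The rapamycin count of 4181 ran from 3211 to 4396 when a strain was left out, and was 3944 without the array labelled igo12 20 min. At 180 min, 3727 became 2369 to 4105 when a strain was left out. The counts that moved were, for the mutants (0), 1386 with culture as a random block, whose p-values cannot be relied on for the reason given above, and 155 with the trend and robust prior. For the untreated mutants (0) they were 3543 with median centring, 229 with offset 0, 222 with the scanner's log ratio and 30 with the filter on both channels.

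For igo12 against Y2092 (61) the count was 160 with median centring, 126 with offset 0, 26 with scale normalization, 165 with the scanner's log ratio and 136 with the series matrix. For rim15 (34) it was 70 with offset 0, 13 with scale normalization, 97 with the scanner's log ratio, 75 with the series matrix and 78 at 120 and 180 min only. Between the mutants (34) it was 55 with offset 0, 16 with scale normalization and 56 with the scanner's log ratio. The overlap (22) was 51, 11, 74, 64 and 43 with offset 0, scale normalization, the scanner's log ratio, the series matrix and 120 and 180 min only. A 1.5-fold rule gave 235, 219, 94 and 105 in the same order of results, and a 3-fold rule 7, 2, 12 and 0, by construction.

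Some mutant differences reversed, none of them past the threshold. CTT1 (0.14) became -0.16 with offset 0, -0.048 at 120 and 180 min, -0.24 with the scanner's log ratio and -0.24 with the series matrix. IGO1 (0.17) became -0.13 with median centring, -0.10 with offset 0, -0.0646 at 120 and 180 min, -0.0725 without 20 min and -0.0846 without the array labelled igo12 20 min. IGO2 (0.12) became -0.43, -0.0281, -0.25, -0.23 and -0.23 in the same settings. GAP1 (-0.52) was 0.12 for rim15 alone and -1.16 for igo12 alone, RIM15 (-0.33) -1.19 and 0.53 in that order, HSP26 (-1.22) 0.10 at 20 and 60 min, and SPI1 (-0.19) 0.27 with median centring. For rapamycin, SPI1 (0.14) became -0.29 with median centring. Apart from the alternatives whose construction is named, the cause was not tested. Brightest probes were not run, since each gene had 1. Signal over background limits the ratios of genes near the floor, whose log2 values grow with the scanner's log ratio.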

Other observations

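All tests in this part were planned. Genes that mark other cell states were measured along with the main lists. Of 6 a-specific genes STE6, the exporter of a-factor, rose with rapamycin (0.70, scanner 1.17) and 0 fell, with a list median of 0.09 (-0.73 with median centring). Of 4 alpha-specific genes 3 fell: MF(ALPHA)1 (-0.996), MF(ALPHA)2 (-0.94) and STE3 (-0.75), with a median of -0.85; at 20 min 2 passed as higher and 0 as lower. Of 13 genes of meiosis and sporulation 6 rose, among them the transcription factor NDT80 (1.06, scanner 2.15), and SPS4 fell (median 0.15, -0.57 with median centring).

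Of 8 auxotrophic markers of laboratory strains, ADE2 (1.06), HIS3 (1.38), LYS2 (0.96) and TRP1 (0.52, scanner 0.81) rose and LEU2 (-1.51), MET17 (-1.41) and URA3 (-0.78) fell, while CAN1 did not pass. Their median was 0.09, and -0.05 without rim15. Across genes, the profiles at 180 min correlated with r = 0.978 between rim15 and igo12, 0.947 between Y2092 and rim15 and 0.928 between Y2092 and igo12; genes are not independent replicates. Lists that had 0 members past either adjustment for the mutants against Y2092 were trehalose (median -0.23), respiration (-0.23), G1/S (-0.21), mitochondrial ribosomal proteins (-0.18), vacuolar proteases (-0.15), meiosis (0.05) and a-specific genes (0.08). The same held for ribosome assembly (-0.11), histones (-0.14), RNA polymerases I and III (-0.05), mRNA decay (0.03), fatty acid oxidation (0.08), Gcn4 targets (0.11) and strain markers (0.09), whose medians changed sign among alternatives.

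When rim15 or igo12 was set apart in place of Y2092, 136 and 153 genes had an unadjusted p under 0.05, against 1228 for Y2092. There are only 3 such splits, too few for a share under 0.05; the highest other count was 153. With the scanner's log ratio the counts were 72 for rim15 and 348 for igo12, against 1034 for Y2092, and 6 genes passed after adjustment with igo12 set apart, against 0 with Y2092 set apart.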
